A study of Mus musculus with 8 samples.

How the data were processed

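Livers of 8 littermate mice were compared, 4 per Manf genotype. The labels do not give the litter or batch of each animal, so neither was modelled. RNA was extracted with Trizol from flash-frozen tissue and made into stranded mRNA libraries, per the labels' protocols. The deposited table gives 1 RPKM value (reads per kilobase of gene length, scaled to library size) per gene and liver, and the authors normalized it by gene length and library size. STAR 2.4.2a, HTSeq and the genome build mm10 are named, per the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here. Samples were grouped by the genotype in the labels, and every column of the table matched 1 sample by name.

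The table held 23300 rows. Rows listed as infinite in all 8 livers (318, among them Plin2, Itgam, Abcc2, Gbp6 and Nnt) and rows named by a bare number (26, the form that gene symbols take when a spreadsheet reads them as dates, 2 of them also infinite) were left out. Of the 22958 other rows 5495 were at 0 in every liver. Symbols matched the GENCODE vM21 annotation of GRCm38 for 98.9% of the named rows, and coordinates come from that annotation.

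RPKM values of low genes move in steps of 1 read. These steps, with the lengths of 1251 genes that have a single transcript in GENCODE, gave the library totals, and 86.8% of those genes gave the same total, within 1 part in 100000. Whole reads, within 0.05 reads, were then recovered for 100.0% of the tested genes. The totals were 62771965, 55935365, 56204936 and 56525608 reads for WT replicates 1 to 4 and 61862424, 57816576, 55315563 and 70897421 reads for MANFHet replicates 1 to 4. The rows with recovered reads held 73.8 to 76.2% of them. At this depth 0.5 RPKM in a gene of 1 kb rests on 27.7 to 35.4 reads.

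Genes with a mean of at least 0.5 RPKM over the 8 livers (10194) were tested in R 4.3.3 with limma 3.58.1 on log2(RPKM + 0.5), with the mean-variance trend, a two-sided moderated test of MANFHet minus WT and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2 scale, which understates the change of genes with low values. Gene lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 33 lists tested. Single values and list means were compared by exact two-sided permutation over all 70 assignments of 8 livers, which cannot give a p below 0.0286. Tables were prepared and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

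The test, the filter, the 39 lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Manf, then up to 12 genes per direction past the threshold with a mean of at least 1 RPKM, leaving out predicted genes, pseudogene names and sex chromosome genes. Because 0 genes passed, the 6 genes per direction with the smallest p stand in their place. It also named up to 4 members of each list past camera, and up to 2 members of the ER chaperone, macrophage, matrix, cytokine and lipogenesis lists whatever their result. Values of 2 of the genes it named are not reported here.

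The scripts were tested on simulated reads with the means, spread and totals of these livers over 10194 genes. With no gene changed 0 genes and 0 lists were called. With 200 genes changed, 59% of those changed 1.5-fold and 93% of those changed 2-fold were called, the median fitted log2 value of the 2-fold genes was 0.88, and 3.80% of calls were unchanged genes. Of 2 lists raised 1.3-fold both were called, with 0 other lists. Genes were simulated independently of each other. In the real livers the estimated correlation between list members ranged from 0.0066 (gluconeogenesis) to 0.92 (MHC class II). The simulation therefore cannot show how often correlated lists are called by chance.

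Alternatives covered the pseudocount, the expression filter, 3 scalings between livers, the variance model, array weights, the replicate number as a block, each liver left out, an estimated inter-gene correlation and fry. Added after the data were seen were limma-voom on the recovered reads and the ER chaperone level of each liver as a covariate.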

Results

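Manf encodes mesencephalic astrocyte-derived neurotrophic factor, a small protein of the endoplasmic reticulum (ER) that cells can also secrete and whose transcription rises under ER stress. The series asked how liver gene expression at 10 months of age differs between mice with both copies of Manf and littermates that carry 1 copy. RNA was sequenced from the livers of 8 C57BL/6 mice, 4 with the Manf +/+ genotype (WT) and 4 with the Manf +/- genotype (MANFHet). Each liver came from a separate animal. The library totals recovered from the steps of the deposited RPKM values lay between 55315563 and 70897421 reads, from 55935365 to 62771965 in WT and from 55315563 to 70897421 in MANFHet. The livers resembled each other closely, with Spearman correlations across genes of 0.976 to 0.988 within a genotype and 0.974 to 0.988 between genotypes. Every liver expressed the Y-linked gene Ddx3y (5.64 to 8.06 RPKM) and had at most 0.00622 RPKM of Xist.

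Manf itself averaged 13.0 ± 5.0 RPKM in WT livers and 6.74 ± 1.75 RPKM in MANFHet livers (SD, n = 4 each), so that the MANFHet mean was 51.7% of the WT mean. The WT livers had 7.99, 17.2, 9.46 and 17.4 RPKM, and the MANFHet livers had 7.39, 6.44, 4.49 and 8.63 RPKM. The ranges overlapped, because MANFHet replicate 4 lay above WT replicate 1, while the other 3 MANFHet livers lay below every WT liver. The log2 fold change on the scale of log2(RPKM + 0.5) was -0.86 (SE 0.28). An exact two-sided permutation test of the difference in mean RPKM gave p = 0.0571 over 70 assignments, where the smallest possible value was 0.0286. In the limma fit over all genes the unadjusted p was 0.0129 and the adjusted p 0.862, so the difference in the targeted gene did not pass the exact test or the adjusted threshold. Between 876 and 3473 reads per liver lay behind these values, which puts the counting error at 1.70 to 3.38% per liver. Manf (ENSMUSG00000032575.16) lies on the minus strand of chromosome 9 from 106838312 to 106891979 in the GENCODE vM21 annotation of GRCm38. That span overlaps Dcaf1, Rbm15b and an antisense transcript. Whether any counted reads lay in the overlap was not tested. The gene annotation and strand setting of the counting are not given in the sources used here, so such reads could not be assigned with certainty.

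**Figure D1:**
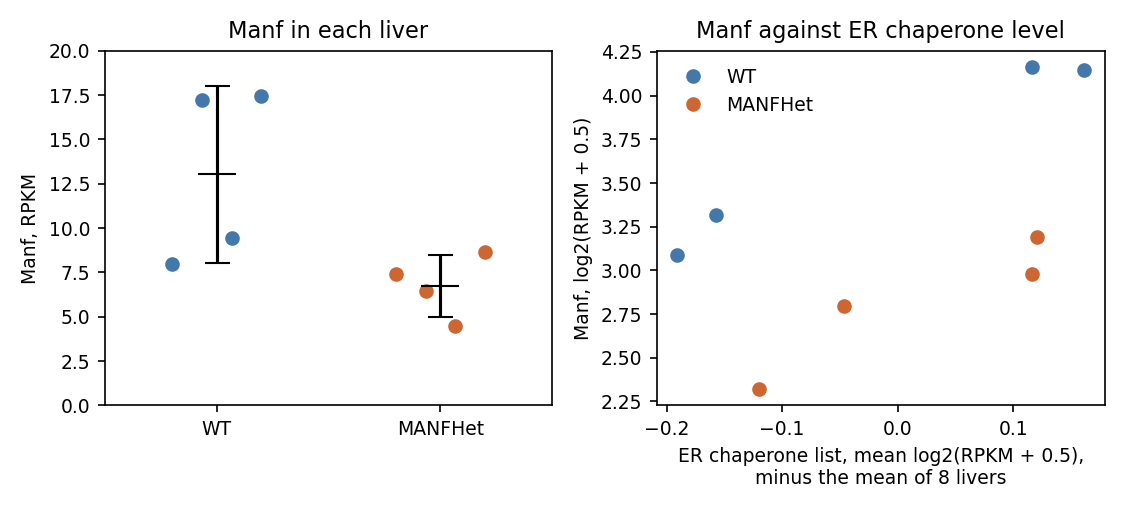
Left, Manf in RPKM in each liver (points) with the mean and SD of each genotype (black). Right, log2(RPKM + 0.5) of Manf against the mean log2 level of 22 ER chaperone genes, centred on the 8 livers. The 4 WT livers span 7.99 to 17.4 RPKM and the 4 MANFHet livers 4.49 to 8.63 RPKM.

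No single gene separated the genotypes after correction for the 10194 genes tested. With limma, 0 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.862. At an unadjusted p under 0.05 there were 556 genes, against 509.7 that chance alone would give, and limma-voom on the recovered reads gave 0 and 551. When each liver was left out the number at an unadjusted p under 0.05 ranged from 339 to 732. It was lowest without MANFHet replicate 2 (268 higher, 71 lower) and highest without MANFHet replicate 3 (603 higher, 129 lower). Of the 556 genes, 459 were higher and 97 lower in MANFHet livers. Scalings that centre the livers on each other gave other balances: with median-of-ratios scaling 180 genes were higher and 221 lower, and with quantile normalization 210 were higher and 203 lower. Over all tested genes 71.2% had a log2 fold change above 0, with a median of 0.05. All 4 MANFHet livers lay above all 4 WT livers for 299 genes and below them for 40, together 3.33% of the tested genes, where chance gives 2.86%. The median standard error of a log2 fold change was 0.09. Data were also simulated with the spread of these livers and 200 genes changed at once. Of these genes, 93% of those changed 2-fold and 59% of those changed 1.5-fold were called. A gene passing alone needs an unadjusted p under 4.9e-06, so these shares do not carry over to a few changed genes.

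The gene with the smallest p among those higher in MANFHet was Mt2, a metallothionein that binds zinc and copper. It averaged 2.19 ± 0.21 RPKM in WT and 7.01 ± 3.20 RPKM in MANFHet (SD, n = 4 each), with a log2 fold change of 1.40 (SE 0.23), and all 4 MANFHet livers exceeded all WT livers. Its limma adjusted p was 0.862 with all livers and 0.0311 without MANFHet replicate 2, the liver with the highest Mt2. Rad9a, a DNA damage checkpoint gene, had a log2 fold change of 0.49, Polr2d, a subunit of RNA polymerase II, 0.34, and Map3k13, a kinase of the stress-activated pathways, 0.52. The values were 0.31 for Mfsd6 and 0.39 for Klhl25. On the lower side, Gbp11, a guanylate-binding protein gene that GENCODE lists as a polymorphic pseudogene, averaged 2.60 ± 0.65 RPKM in WT and 1.18 ± 0.14 RPKM in MANFHet. Tstd1 had 14.7 ± 1.37 against 10.1 ± 1.01 RPKM, and the chemokine gene Ccl9 8.77 ± 1.07 against 5.92 ± 1.23 RPKM. Clec2h had a log2 fold change of -0.95 and Rlf of -0.34. Mir3058 had -0.53, with only 4 to 10 reads per liver. All of these genes are named by their rank, and none passed the adjusted threshold.

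**Figure D2:**
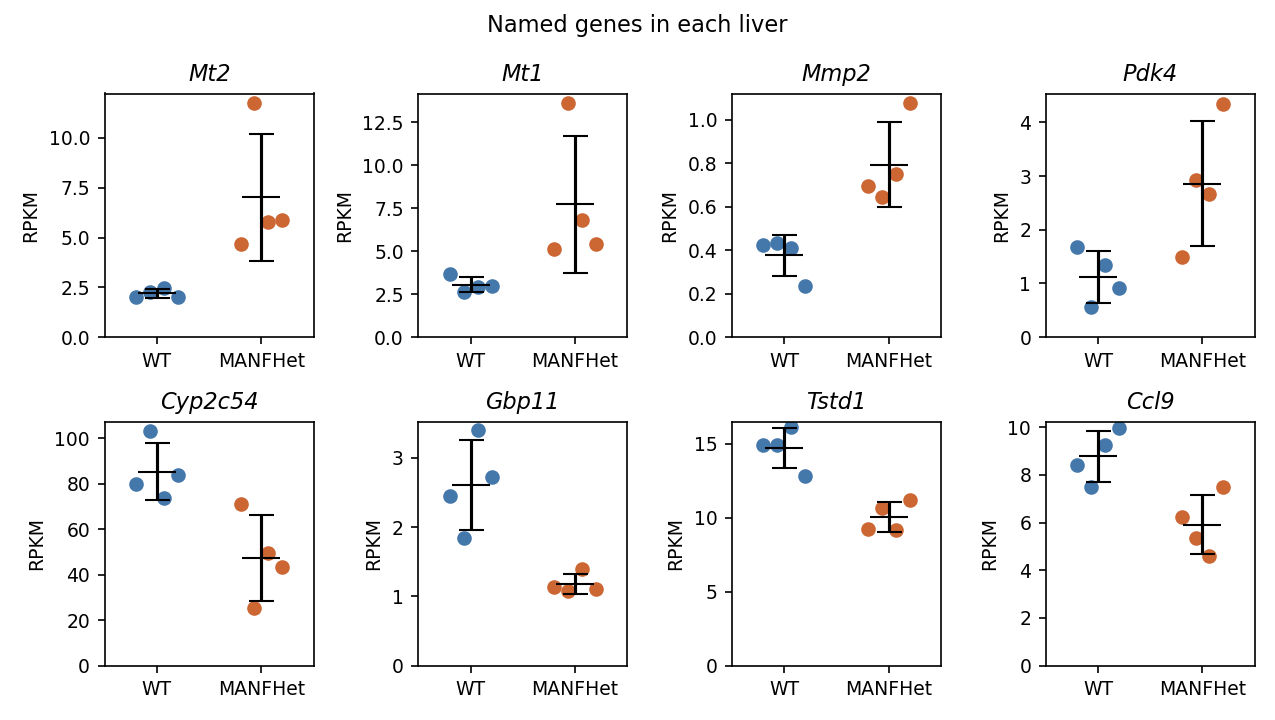
RPKM of 8 named genes in each liver (points), with the mean and SD of each genotype (black) and every axis starting at 0. In Mt2 the 4 MANFHet livers lie above the 4 WT livers, and in Gbp11 below them; neither gene passed the threshold over all genes.

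The ER genes closest to the known function of Manf did not separate the genotypes. Of 22 tested ER chaperones and folding enzymes 15 were higher and 7 lower in MANFHet, 0 at an unadjusted p under 0.05, with a median log2 fold change of 0.05, near the 71.2% and 0.05 over all tested genes. The median was -0.002 without WT replicate 1, 0.02 without WT replicate 3 and 0.03 without MANFHet replicate 1, and 0.09, 0.08 and 0.09 without WT replicate 2, WT replicate 4 and MANFHet replicate 3. The camera test, which sets a list against the other genes and not against 0, called the list lower, with an adjusted p of 0.649. Erp44, a folding enzyme, had 13.7 ± 0.48 RPKM in WT and 15.0 ± 0.89 RPKM in MANFHet, and Erp29 had 3.74 ± 0.33 and 4.12 ± 0.19 RPKM. Of 22 genes of the unfolded protein response and ER-associated degradation 10 were higher and 12 lower, with an adjusted p of 0.212.

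Of the 39 gene lists fixed in advance 33 had at least 5 tested members. With the preset inter-gene correlation of 0.01, 12 of these passed the camera test. Relative to the other tested genes, 5 of the 12 were higher and 7 lower in MANFHet. The median log2 fold change over all tested genes was 0.05. With an estimated correlation 0 lists passed and the smallest adjusted p was 0.35, and with fry 0 lists passed and the smallest adjusted p was 0.506. Exact permutation tests of the list means gave p = 0.0286 for the matrix and glucocorticoid lists, 0.0571 for fatty acid oxidation, 0.0857 for periportal genes, 0.143 for lipid droplets and for p53 targets, 0.286 for hepatocyte identity and 0.4 for xenobiotic metabolism. They gave 0.629 for male-high genes, 0.657 for Kupffer cells, 0.743 for bile acid genes and 0.886 for ribosomal proteins, so 2 lists were under 0.05. These p values were not adjusted over the 33 lists, and 4 against 4 livers separate by chance in 2.86% of cases. Adjusted over all genes 0 members of any list passed.

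Genes of fibrosis and the extracellular matrix were higher in MANFHet livers in 26 of 28 tested members, with a median log2 fold change of 0.36. At an unadjusted p under 0.05 there were 13 members, all higher, and 1 passed when adjusted over the list alone, against 0 over all genes. The 13 became 7 without WT replicate 4, 8 without MANFHet replicate 4 and 9 with a mean of at least 1 RPKM. The member that passed was Mmp2, a gelatinase that cleaves collagen, with 0.38 ± 0.09 RPKM in WT and 0.79 ± 0.20 RPKM in MANFHet. Vim, an intermediate filament of mesenchymal cells, had 3.44 ± 0.48 against 5.31 ± 1.13 RPKM, and Col1a2, a chain of type I collagen, 0.86 ± 0.14 against 1.57 ± 0.56 RPKM. Col6a2 had 0.38 ± 0.05 against 0.69 ± 0.20 RPKM. Camera gave an adjusted p of 3.68e-08, and the adjusted p was 0.45 with an estimated correlation. An exact permutation test of the list means gave p = 0.0286, the smallest that 4 against 4 livers allow. MANFHet replicate 4 had the highest list mean, and without it the median log2 fold change was 0.19. That liver also stood apart in clock genes, with Dbp at 19.7 RPKM against 32.5 to 41.4 RPKM in the others. Markers of hepatic stellate cells, the main matrix-producing cells of the liver, were higher in 16 of 17 tested members, with a median of 0.15 and an adjusted p of 0.174. The stellate and matrix lists as fixed share Dcn and Pdgfrb, so they are not separate results. Without MANFHet replicate 4 the stellate median was 0.02 and camera called the list lower (adjusted p = 0.959), and without MANFHet replicate 3 the median was 0.27 and the list passed as higher (adjusted p = 0.00105). It also passed as higher with median-of-ratios scaling (adjusted p = 0.0110) and quantile normalization (0.0304). With an estimated correlation and all 8 livers the camera adjusted p of the stellate list was 0.835.

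Of 34 genes of fatty acid oxidation and PPAR-alpha targets 33 were higher in MANFHet livers, 9 of them at an unadjusted p under 0.05, with a median log2 fold change of 0.19. Pdk4, which restrains glucose oxidation, had 1.12 ± 0.48 RPKM in WT and 2.86 ± 1.17 RPKM in MANFHet. Log2 fold changes were 0.42 for Cyp4a31 and 0.47 for Pex11a. The camera adjusted p was 2.78e-06, and the adjusted p was 0.45 with an estimated correlation. Of 24 genes of lipid droplets and fatty acid uptake 22 were higher, 4 at an unadjusted p under 0.05, with a median of 0.23. G0s2, an inhibitor of triglyceride lipase, had 92.4 ± 29.5 against 151.3 ± 29.9 RPKM and Plin5, a droplet coat protein, 15.8 ± 1.47 against 21.6 ± 4.35 RPKM. Mgll had a log2 fold change of 0.32 and Slc27a4 of 0.15. For this list camera gave an adjusted p of 0.000734, and the adjusted p was 0.45 with an estimated correlation. Without WT replicate 2 its median was 0.13. De novo lipogenesis did not pass (adjusted p = 0.632), with 19 of 25 members higher, Me1 at a log2 fold change of 0.62 and Mid1ip1 at -0.54.

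In the glucocorticoid and fasting list 17 of 20 genes were higher, with a median log2 fold change of 0.22, a camera adjusted p of 0.0303 and an adjusted p of 0.45 with an estimated correlation. Adjusted over the list alone 2 members passed, Mt2 and its neighbour Mt1, which had 3.05 ± 0.45 RPKM in WT and 7.73 ± 3.99 RPKM in MANFHet, against 0 over all genes. Both also belong to the acute phase list, which did not pass (adjusted p = 0.425). Gadd45b had a log2 fold change of 0.42 and Cdkn1a of 0.74. The call was lost without WT replicate 3 (adjusted p = 0.3, median 0.07) and without MANFHet replicate 2 (adjusted p = 0.0807, median 0.13), and with a mean of at least 1 RPKM (0.0655). The list of p53 targets and senescence was higher in 14 of 17 genes, with a median of 0.13, a camera adjusted p of 0.0319 and an adjusted p of 0.653 with an estimated correlation. Log2 fold changes were 0.32 for Bbc3 and 0.22 for Igfbp7. That call was lost without WT replicate 2 (0.452), WT replicate 3 (0.0975) or MANFHet replicate 4 (0.133), each an adjusted p. It was also lost with no expression filter (0.0821), a mean of at least 1 RPKM (0.0821), the sum of values scaled (0.0526) and array weights (0.114).

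In the list of xenobiotic metabolism 18 of 23 genes were lower in MANFHet, 4 at an unadjusted p under 0.05, with a median log2 fold change of -0.24. Cyp2c54 had 85.3 ± 12.7 RPKM in WT and 47.3 ± 18.9 RPKM in MANFHet, Cyp2c50 158.7 ± 14.6 and 114.1 ± 32.1 RPKM, and Cyp1a2 210.8 ± 37.5 and 151.7 ± 42.9 RPKM. The 2 Cyp2c genes belong to a family of near-identical copies, so their reads may be shared. Ces2a, a carboxylesterase gene, had a log2 fold change of -0.32. With camera the adjusted p was 1.11e-08, and the adjusted p was 0.35 with an estimated correlation. The median was -0.09 without WT replicate 4 and -0.15 without MANFHet replicate 4. Among periportal hepatocyte genes 16 of 17 were lower, with a median of -0.10, a camera adjusted p of 3.68e-08 and an adjusted p of 0.35 with an estimated correlation. Pigr, the receptor that carries IgA into bile, had 336.9 ± 15.0 against 266.0 ± 39.6 RPKM, and log2 fold changes were -0.39 for Hal, -0.36 for Cps1 and -0.19 for Gls2. The median was -0.05 without WT replicate 4, -0.06 without MANFHet replicate 4, -0.17 without WT replicate 2 and -0.15 without MANFHet replicate 3.

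Hepatocyte secretory and identity genes were lower in 19 of 26 members, 0 of them at an unadjusted p under 0.05, with a median of -0.05. Foxa2, a liver transcription factor, had 10.7 ± 3.44 against 8.02 ± 0.95 RPKM, Otc 93.0 ± 4.58 against 81.5 ± 12.6 RPKM, and Apob a log2 fold change of 0.16. The camera adjusted p was 4.64e-06, with 0.417 as the adjusted p under an estimated correlation, and without MANFHet replicate 4 (adjusted p = 0.0539) or with quantile normalization (0.0958) the call was lost. The median was -0.02 without WT replicate 2 or MANFHet replicate 4 and -0.10 without WT replicate 3. Bile acid genes were mixed, with 10 higher and 14 lower. Abcb4, the canalicular phospholipid transporter, had a log2 fold change of 0.32, Nr0b2, a nuclear receptor that represses bile acid synthesis, -0.45, Akr1d1 -0.30 and Cyp8b1 0.76. For that list camera gave an adjusted p of 0.00455, and the adjusted p was 0.35 with an estimated correlation. The bile acid call was lost without WT replicate 1 (adjusted p = 0.0845) without MANFHet replicate 4 (adjusted p = 0.0748), with median-of-ratios scaling (0.0585) and with quantile normalization (0.403). The bile acid median was -0.05 with all livers, lay above 0 without WT replicate 1, WT replicate 2 or MANFHet replicate 3, and was -0.03 without WT replicate 3, -0.08 without WT replicate 4, -0.10 without MANFHet replicate 1 and -0.02 without MANFHet replicate 2.

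Markers of Kupffer cells, the resident macrophages of the liver, were lower in 19 of 22 members, 0 of them at an unadjusted p under 0.05, with a median log2 fold change of -0.13. Marco, a scavenger receptor, had 6.95 ± 6.16 RPKM in WT and 1.99 ± 1.65 RPKM in MANFHet, a spread larger than the difference, and log2 fold changes were -0.48 for Timd4, -0.21 for Aif1 and -0.13 for Slc40a1. The camera adjusted p was 1.12e-05, and the adjusted p was 0.651 with an estimated correlation. MANFHet replicate 3 decided this call: without it the adjusted p was 0.489 and the median 0.09. The median was -0.04 without WT replicate 2, -0.22 without WT replicate 3 and -0.26 without MANFHet replicate 4. Inflammatory cytokines and chemokines did not pass (adjusted p = 0.0795), with a median of 0.06 beside a test that called the list lower than other genes. That median was -0.10 without MANFHet replicate 4, -0.04 without WT replicate 3, 0.04 without WT replicate 1, 0.12 without WT replicate 2 and 0.11 without MANFHet replicate 3. Cxcl13 had 1.17 ± 0.82 against 0.36 ± 0.23 RPKM. The cytokine list passed as lower without WT replicate 1 (adjusted p = 0.0312), WT replicate 3 (0.0342) or MANFHet replicate 4 (0.0029).

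Liver genes with higher expression in males were lower in 17 of 24 members, with a median of -0.09, a camera adjusted p of 0.000223 and an adjusted p of 0.45 with an estimated correlation. Hsd3b5 had 59.3 ± 48.7 RPKM in WT and 25.8 ± 29.9 RPKM in MANFHet, and log2 fold changes were -0.20 for Ugt2b1, -0.54 for Cyp4a12b and -0.35 for C8b. Without WT replicate 2 the call was lost (adjusted p = 0.124) and the median was 0.05. The call was also lost with quantile normalization (0.166), and the median was -0.22 without WT replicate 4, -0.19 without MANFHet replicate 1 and -0.06 without WT replicate 3. Cytosolic ribosomal protein genes passed with 19 members higher and 20 lower and a median of 0.00 (camera adjusted p = 0.00381, adjusted p = 0.835 with an estimated correlation). Log2 fold changes were -0.06 for Rpl7, -0.07 for Rps18, -0.05 for Rpl23 and 0.06 for Rplp0, which was -0.01 under median-of-ratios scaling. The ribosomal call was lost and turned to higher without WT replicate 2 (adjusted p = 0.968) or MANFHet replicate 4 (adjusted p = 0.964) and with array weights (0.721), and lost with quantile normalization (0.906). Its median ranged from -0.03 to 0.03 when each liver was left out. Median-of-ratios scaling moved the medians of several lists by over 1.5-fold, to -0.17 for periportal, -0.12 for hepatocyte identity, -0.20 for Kupffer cell, -0.16 for male-high, -0.12 for bile acid, -0.08 for ribosomal, 0.12 for fatty acid oxidation and 0.06 for p53 genes. Array weights gave -0.03 for hepatocyte identity and 0.15 for lipid droplets, and quantile normalization gave -0.02 for hepatocyte identity and 0.08 for p53 genes.

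**Figure D3:**
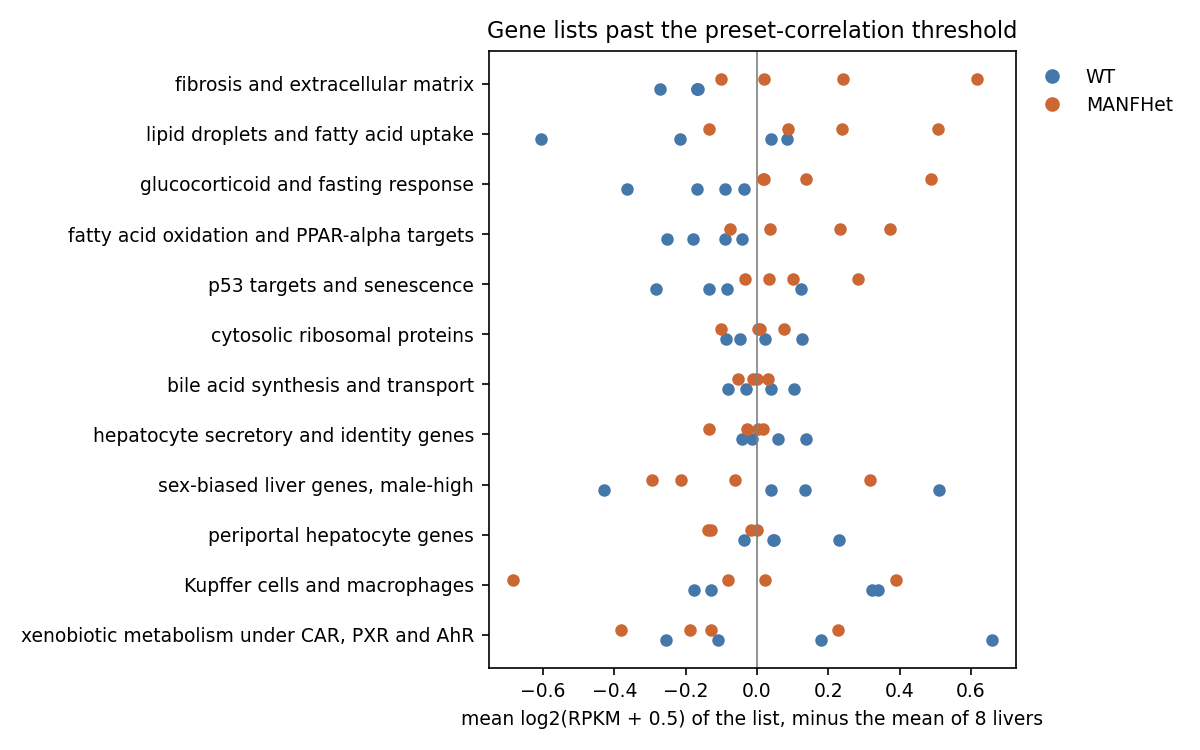
Mean log2(RPKM + 0.5) of each of the 12 lists that passed with the preset correlation, centred on the 8 livers, 1 point per liver. In the matrix and glucocorticoid lists the 4 MANFHet points lie above the 4 WT points, in the other 10 the genotypes overlap, and 0 lists passed with an estimated correlation.

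The other lists did not pass. Camera adjusted p was 0.0525 for the cell cycle, 0.0619 for the circadian clock, 0.0849 for gluconeogenesis and glycogen, 0.165 for cholesterol synthesis and 0.174 for pericentral hepatocyte genes. It was 0.186 for MHC class II, 0.212 for cholangiocytes, 0.334 for NRF2 targets, 0.362 for immediate early and heat shock genes, and 0.542 for both endothelium and the interferon response. It was 0.59 for female-high genes and 0.632 for monocyte-derived macrophages, adjacent tissue and oxidative phosphorylation. The lists for T and NK cells (1 tested member), B and plasma cells (2), neutrophils (4), sex chromosome genes (4), red blood cells (1) and mitochondrially encoded genes (0) had too few tested members. Of the 21 tested lists that did not pass, 13 passed when 1 liver was left out, most of them without MANFHet replicate 3 or 4, and 5 passed under another setting with all 8 livers: the cell cycle, the circadian clock, cholesterol synthesis, stellate cells and MHC class II.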

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

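Of the tests in this part, those on GC content and length, and on the share of higher genes in other splits, were chosen before their result was seen, and the others only after. The settings without 1 liver and with other scalings were planned, but their use as tests of an explanation was not. Among 196 groups of 4 livers examined, 12 held a liver far from the other 3 (6.12%, where chance gives about 5%).

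In MANFHet, Mt2 was at 11.7 RPKM in replicate 2 against 4.67 to 5.85 in the others, Gbp11 at 1.39 in replicate 3 against 1.08 to 1.13, Cyp4a12b at 20.6 in replicate 1 against 7.30 to 9.07, and Bbc3 at 2.32 in replicate 2 against 2.59 to 2.64. In WT, replicate 4 stood apart in Klhl25 (3.73 against 2.85 to 2.95 RPKM), Aif1 (3.44 against 2.21 to 2.38) and Mmp2 (0.24 against 0.41 to 0.43), and replicate 1 in Gadd45b (0.20 against 0.56 to 0.57). The centred mean log2 of the matrix list was -0.27 in WT replicate 4 against -0.17 to -0.16 in the other WT livers, and that of the circadian list -0.085 in WT replicate 1 against 0.04 to 0.06. The pericentral list was at -0.11 in MANFHet replicate 2 against 0.02 to 0.03. The library of WT replicate 1 held 62771965 reads against 55935365 to 56525608 in the other WT livers.

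Manf ranged from 7.99 to 17.4 RPKM within WT, so that the genotypes overlapped, and within genotypes it followed the mean of the ER chaperone list (Pearson r = 0.97, exact permutation p = 0.00347; Spearman rho = 0.952, exact permutation p = 0.0139; r = 0.957 without the 2 livers farthest from the median, 8 livers in all). A candidate explanation is that the ER state of each liver sets the level from which the genotype difference starts. At an equal ER chaperone level the log2 fold change was -0.96 (SE 0.09), or 51.3% of WT on the scale of RPKM + 0.5. That percentage is not a ratio of mean RPKM. The log2 fold change was -0.86 (SE 0.28) without the ER chaperone genes as a covariate. Since these genes were picked from the labelled genotypes, each of the 35 splits was given whichever of the 33 tested lists separated Manf best, and 1 of them, the labelled one, separated it this well (statistic 10.7, highest other 5.24), which argues against labels swapped between the genotypes. With this covariate, chosen because Manf was seen to follow these genes, Manf was the only gene past the limma threshold with all 8 livers (adjusted p = 0.0383, range over the other settings 0.686 to 1), but 5 of the 35 splits gave at least 1 gene (real value 1, highest other 2), so chance cannot be excluded for that count. Without MANFHet replicate 1 the gene that passed was Clec2h (adjusted p = 0.0318). Leaving out any 1 liver lifted the adjusted p of Manf to between 0.055 and 0.301. In the same fits its unadjusted limma p was 5.39e-06 to 2.95e-05, with the covariate chosen as described, and its log2 fold change stayed between -1.02 and -0.92.

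The matrix list was higher in MANFHet, and 2 of the 35 splits gave a camera p as small (-log10 p of 8.48, highest other 8.69), so chance cannot be excluded. MANFHet replicate 4 carried much of it: without that liver the median log2 fold change was 0.19 in place of 0.36. The other 3 MANFHet livers still lay above all WT livers in the list mean (exact permutation p = 0.0286), so that liver was not the only one above WT. That order was fixed by the separation with all 8 livers, so the p is no separate test of that liver as the whole cause. A lower share of hepatocytes would raise the markers of all other cells alike and cannot be told apart. The matrix list mean moved above the macrophage mean by 0.57 and above the cholangiocyte mean by 0.54 (exact permutation p = 0.0286 for each). With single livers left out these differences stayed at 0.46 to 0.66 and 0.41 to 0.64, but the p rose as high as 0.0857 and 0.0571. The difference was 0.32 against endothelium, 0.28 against monocyte-derived macrophages and 0.17 against MHC class II (exact permutation p = 0.0571, 0.114 and 0.286). Medians of other cells went both ways, with each liver left out in brackets: 0.26 for MHC class II (0.08 to 0.40), 0.17 for monocyte-derived macrophages (0.04 to 0.29), 0.15 for stellate cells (0.02 to 0.27), 0.02 for endothelium (-0.07 to 0.15), 0.008 for cholangiocytes (-0.03 to 0.05), -0.13 for Kupffer cells (-0.26 to 0.09), and, in lists of 1 to 4 tested members, -0.22 for T and NK cells, -0.21 for B and plasma cells and -0.06 for neutrophils. More stellate cells cannot be told apart from more matrix expression per cell either, with the genotype difference of the matrix list 0.25 above that of stellate markers outside it (exact permutation p = 0.0571), and the genotype itself stays among the open explanations.

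Most genes at an unadjusted p under 0.05 were higher in MANFHet (82.6%). After each liver's trend on GC content and gene length was removed, for the 99.1% of genes with a value, the share was 84.3%. That step kept each liver's mean level, so it cannot decide on a bias that acts through that level. Scaling of the RPKM cannot be told apart from a real shift: the share was 44.9% under median-of-ratios scaling, but that scaling centres the fold changes (median over all genes -0.014 in place of 0.048), which by itself evens the balance. In 3 of the 35 splits the share lay as far from an even balance (32.6 percentage points, highest other 38.7), so chance cannot be excluded either. No biological explanation was tested.

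Other splits bear on the counts as well. With 0 genes in the real split all 35 splits give at least as many by construction (highest other 3), so they cannot decide on that count. Of the 35 splits, 14 gave as many as the 556 genes at an unadjusted p under 0.05 (highest other 1414), and 21 gave as many as 12 lists (highest other 19). Chance can be excluded for neither of these counts.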

How the results depend on the processing

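Among the tests in this part, limma-voom on recovered reads and the ER chaperone covariate were chosen after the data were seen. The count of 0 genes past the limma threshold was the same under every planned setting with all 8 livers and with voom. It was 1 with the ER chaperone covariate (Manf) and ranged from 0 to 1, total and higher, when each liver was left out: without MANFHet replicate 2, 1 gene, Mt2, passed; the cause was not tested. The log2 fold change of Manf (Manf expression) kept its direction in every setting, from -1.05 to -0.69. Its adjusted p passed only with the covariate. Its unadjusted limma p stayed under 0.05 in each of the 21 other settings compared, the covariate among them. The 12 lists past the threshold became 0 with an estimated correlation and 0 with fry, and ranged from 11 to 18 when each liver was left out. The estimate takes the correlation between members from these livers. It was 0.016 for bile acid genes, near the preset, yet their unadjusted camera p rose from 0.00138 to 0.0226. For gluconeogenesis it was 0.0066, below the preset, and the unadjusted camera p rose from 0.0412 to 0.0797. A higher correlation thus did not account for every rise in p. The loss of the 12 calls with the estimate cannot be read as the effect of correlation between members alone. Fry also tests a list against no change, not against the other genes, and whether this or the correlation ended its calls was not tested. Without the expression filter 978 genes reached an unadjusted p under 0.05, from more genes tested.

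Of the 12 lists past the threshold 1 turned direction in at least 1 of 21 camera settings, and of the 21 tested lists that did not pass 16 did. Among the lists and genes with named members 3 lists and 1 gene turned, and the cause was not tested, except that fry gives a direction against 0 and camera against the other genes. Rplp0 was at -0.011 under median-of-ratios scaling. When turned, the adjusted p of the list ER chaperones and folding enzymes was 0.563 with quantile normalization, 0.484 with array weights, 0.378 without WT replicate 2, 0.399 without WT replicate 4, 0.874 without MANFHet replicate 2, 0.849 without MANFHet replicate 3 (0.116 to 0.874 over the livers left out) and 0.926 with fry. For the list de novo lipogenesis it was 0.56 with median-of-ratios scaling, 0.182 with quantile normalization, 0.319 without WT replicate 3, 0.154 without MANFHet replicate 3 (0.154 to 0.547 over the livers left out) and 0.926 with fry. For the list cytosolic ribosomal proteins it was 0.721 with array weights, 0.968 without WT replicate 2 and 0.964 without MANFHet replicate 4 (1.63e-06 to 0.968 over the livers left out).

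Replicate numbers did not pair the livers: livers of the same number had correlations of their deviations of 0.08, -0.04, 0.08 and -0.13, and 1 of 8 livers correlated best with the liver of its own number. With the replicate number as a block 0 genes and 14 lists passed, and the log2 fold change of Manf was -0.86. Sex as a covariate was not run, since all 8 livers express Y-linked genes. Depth limits genes near 0.5 RPKM, where a gene of 1 kb has about 28 to 35 reads.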

Other observations

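The genes in this part were chosen after their values were seen. Genes of sex-dependent liver metabolism varied widely between livers of 1 genotype, although all 8 livers express Y-linked genes. Cyp2b9, a gene higher in female liver, ranged from 0.99 to 51.5 RPKM in WT and from 2.4 to 17.4 RPKM in MANFHet, and Cyp2a4 from 0.43 to 17.1 and from 0.87 to 15.1 RPKM. Hsd3b5, a gene higher in male liver, ranged from 13.2 to 126.1 RPKM in WT and from 4.00 to 68.4 RPKM in MANFHet. The lipid droplet gene Cidea ranged from 0.25 to 31.7 RPKM in WT and from 1.18 to 48.6 RPKM in MANFHet.

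Clock genes set MANFHet replicate 4 apart. It was the highest or lowest of the 8 livers for 17 of 22 clock genes, where 5.5 would fall to each liver by chance and no other liver reached more than 5. Of the 22 genes 19 passed the expression filter, and no test was run on the count. Under the rule for distant livers above, 0 of the 12 flagged were MANFHet replicate 4. Arntl was at 0.70 RPKM there against 0.08 to 0.22 in the others, Npas2 at 0.16 against 0.02 to 0.03, Dbp at 19.7 against 32.5 to 41.4, Ciart at 1.96 against 3.45 to 7.92 and Usp2 at 2.34 against 5.57 to 15.3. The same liver had Tubb2a at 145.7 against 16.0 to 46.9 RPKM, the deepest library (70897421 reads) and the lowest array weight (0.49).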
